A study of Homo sapiens with 8 samples.

How the data were processed

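The series holds 8 arrays of RNA from 2 human lung adenocarcinoma cell lines, HCC4019 and NCI-H3255 (H3255 below). In each line, cells received a pool of small interfering RNAs (siRNAs) against NKX2-1, named by its older symbol TITF1 in the labels, or a non-targeting pool. NKX2-1 is a homeodomain transcription factor of lung and thyroid. Per the labels, 400000 cells were seeded per well, the siRNA was used at 100 nM with 6 ul of transfection reagent, and RNA was taken after 72 h. Each of the 4 groups has 2 arrays, which the labels call biological replicates. No label says more about how the cultures were separated, so p-values here measure the spread between these samples.

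The arrays are Illumina HumanHT-12 v3.0 expression BeadChips, read in 1 colour. Per the file headers, the deposited table holds for each array a bead-averaged signal intensity per probe on the linear scale, together with a detection p-value that compares the probe with the array's negative control beads. The authors exported these values from GenomeStudio, per the labels. The intensity values are not background-subtracted and not normalized, since the array medians run from 126.6 to 175.0. The detection p-values, deposited beside the intensities, move in steps of 1 in 759. A second deposited table holds the authors' processed intensity values, which were log2 transformed and quantile-normalized in Partek Genomics Suite 6.5 per the labels. That table was found on the linear scale, and its column medians run from 153.36 to 153.41. Its ranks equal those of the same array in the first table, and how it was turned back from log2 is not given in the sources used here. The files name no chip position and no scan, so neither was used as a batch.

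The unnormalized table has 48803 probes, of which 48797 are also in the authors' processed table. In the platform annotation, 28093 probes have 1 gene symbol, 13 have several and 20697 have none. Symbols were updated through Entrez identifiers where the reference table holds them, which was so for 28054 probes. Results are named only from probes with 1 symbol. The 12 genes tested that lie on chromosome Y or are XIST are counted but not listed.

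Background was corrected with limma's normexp model, with the mean and spread of the background inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. A probe was kept when its detection p was under 0.05 on both arrays of at least 1 group, which left 18435 probes. Among the kept probes of a gene the one with the highest mean was used, giving 11615 genes, 3074 of which had more than 1 kept probe. A linear model with the 4 groups was fitted to all 8 arrays together in limma 3.58.1 under R 4.3.3, so that both lines share 1 estimate of the spread. The fit leaves 4 residual degrees of freedom, and empirical Bayes added 3.89. Contrasts were the siRNA effect in each line, the difference between those effects (H3255 minus HCC4019), their average, and the control arrays of H3255 against those of HCC4019. Adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05, over all 11615 genes unless stated otherwise. Changes are log2 differences, knockdown minus control, given with the standard error (SE).

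An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so no result here rests on permutation of a single gene. Where no probe of a gene was detected on any array of 1 group, the change is given as "at least N-fold". The bound sets the bright group's mean against a floor made from the lowest normalized value of a detected probe on each array of the dim group, or the dim probe's own value if that is higher. The bound holds for the background-corrected values, and values without that correction are smaller. No fold is given where neither group detected the gene.

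Before the data were examined, 24 gene lists with 381 genes were written, of which 264 were tested and 33 had no probe of their symbol. They cover alveolar type II cells, airway secretory and ciliated cells, gastrointestinal differentiation, lung transcription factors, secreted lung proteins, receptor tyrosine kinases and their ligands, output of the ERK pathway, cell cycle, p53 targets, epithelial junctions, mesenchymal genes, interferon response, NF-kB and chemokines, MHC class II, the unfolded protein response, sterol and fatty acid synthesis, hypoxia and glycolysis, thyroid and brain genes linked to NKX2-1, squamous, neuroendocrine, fibroblast, leukocyte and endothelial markers, and reference genes. Each list was tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry. No list passed in any contrast when the correlation was estimated. The lowest adjusted p was then 0.394 in HCC4019, 0.192 in H3255, 0.643 for the difference between lines and 0.108 for the average. That version was stricter even where the estimate was low. For ERK output genes in HCC4019 the estimate was 0.0038, under 0.01, yet the camera p rose from 0.0044 to 0.041. A call lost in that version therefore does not show that correlation between genes made the call. The estimates of the other lists called in HCC4019 were above 0.01, at 0.036 (alveolar type II), 0.063 (cell cycle) and 0.087 (NF-kB and chemokines). For these the part played by correlation cannot be told.

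Named genes were fixed by rule before the data were examined. In each line these are NKX2-1, then the 10 largest rises and 10 largest falls among genes past the threshold whose knockdown arrays both lie beyond both control arrays. For the average the rule takes the 10 largest each way past the threshold whose knockdown arrays lie beyond the control arrays in that direction in both lines, and for the difference between lines and the control arrays the 5 largest each way. From each gene list it takes up to 4 members with the largest change. Other genes are named only as members of lists or where a count is small, after their values were seen. Symbols starting with LOC or HS. are not named.

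The procedure was tested on simulated arrays built from the mean of each gene in each line. Spreads were drawn at random from the distribution that limma fitted to these data, with independent normal noise. There were 11615 genes, 200 of them changed in the H3255 contrast, over 20 simulations. Of the genes changed by a log2 of 0.5, 1 and 2, it recovered 1.61%, 52.0% and 95.5%, and 4.92% of its calls were false. This noise follows the model that limma assumes, so the false share checks the procedure and does not measure the error rate on the real arrays. Alternatives covered the background correction, the normalization, the authors' processed values, the detection filter, the probe rule, replicate number as a block, fitting each line alone, the variance model, array weights, the threshold, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.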

Results

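Expression was measured on 8 arrays, 2 for each combination of cell line (HCC4019 or H3255) and siRNA (against NKX2-1 or non-targeting). Between 16989 and 18120 probes were detected per array, or 34.8% to 37.1% of all probes. Across the genes tested, arrays of the same group correlated at 0.989 to 0.992, arrays of the same line with the other siRNA at 0.979 to 0.989, and arrays of different lines at 0.821 to 0.831. The median SD between the replicates of a group lay between 0.114 and 0.128 on the log2 scale.

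The target of the siRNA was examined first. NKX2-1 (Entrez gene 7080, chromosome 14) was read by 2 probes, both detected on all 8 arrays, and every knockdown array lay below both control arrays of its line on both probes. On the dimmer probe, 34.0% of the control level was left in HCC4019 and 51.6% in H3255, and on the brighter probe 59.6% and 64.0%. With the mean of the 2 probes, NKX2-1 fell by 1.15 ± 0.128 (SE, log2) in HCC4019 (limma, adjusted p = 0.0368) and by 0.80 ± 0.128 in H3255 (limma, adjusted p = 0.0159). The brighter probe, which the probe rule selects, gave -0.75 ± 0.177 in HCC4019 and -0.64 ± 0.177 in H3255, neither past the threshold (limma, adjusted p = 0.194 and 0.0838). The fall did not differ detectably between lines (mean of the probes, H3255 minus HCC4019, 0.35 ± 0.181, limma, adjusted p = 0.373).

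**Figure D1:**
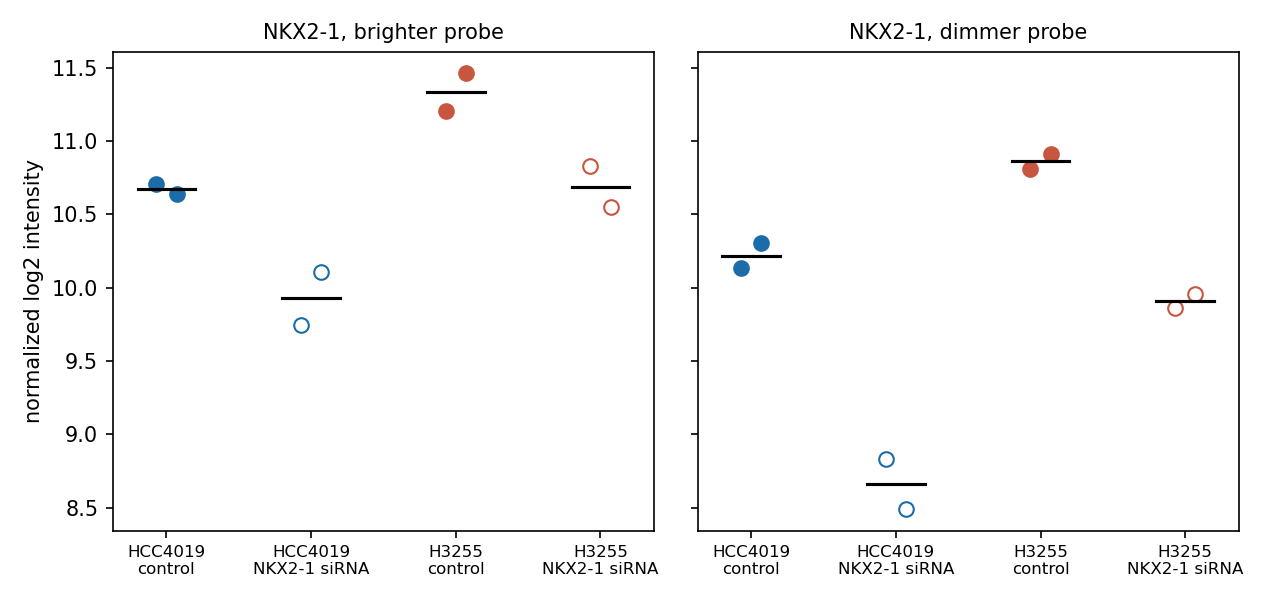
Normalized log2 intensity of NKX2-1 on each of the 8 arrays, for its brighter (left) and dimmer (right) probe, with a point per array and a line at the mean of each group of 2. Knockdown arrays (open points) lie below the control arrays (filled) of the same line on both probes, with 34.0% of the control level left on the dimmer probe in HCC4019 and 51.6% in H3255.

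The first comparison asked which genes changed with NKX2-1 siRNA in HCC4019. The largest fall was in SFTPB, which encodes surfactant protein B, at -1.75 ± 0.197, or 3.36-fold lower. Also lower were CEMIP, a hyaluronan-degrading protein (-1.18), LRRN4 (-1.16), DMBT1, a mucosal scavenger receptor protein (-1.09), and the keratin pseudogene KRT16P2 (-1.01), whose probes may read the closely related keratin genes and so stay uncertain. Genes that rose were led by GSTA2, a glutathione transferase (1.72 ± 0.148, or 3.30-fold), RARRES1 (1.66), the secreted phospholipase PLA2G10 (1.48), the calcium-binding protein S100P (1.45) and the urea cycle enzyme ASS1 (1.35). AXIN2, a Wnt target and negative regulator, was not detected on the control arrays and rose at least 2.28-fold (limma, adjusted p = 0.0464). TCN1 (1.26), SLX4IP (1.13, detected on 1 of the 2 control arrays), CD82 (1.12) and TLR1 (1.07) completed the set. In all, 15 of 11615 genes passed the threshold, 10 higher and 5 lower, with adjusted p from 0.0358 to 0.0487 in limma, and 1313 genes had an unadjusted p under 0.05. In 42.7% of the genes the knockdown and control arrays did not overlap, where chance gives 33.3%.

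Among the gene lists, alveolar type II genes, those of the surfactant-producing cells of the lung, were lower in HCC4019 (median -0.41, camera adjusted p = 2.0e-04, adjusted p = 0.394 with an estimated correlation). Of 15 measured members 1, SFTPB, passed over all genes and 7 when adjusted over the list alone, all 7 lower; of the 14 members other than NKX2-1, the target itself (counted after the results were seen), 1 passed over all genes and 4 adjusted over the list alone. SFTPA1, surfactant protein A (limma, adjusted p = 0.112), and the surfactant-processing protease NAPSA (-0.76, adjusted p = 0.0972) did not pass over all genes. SFTPA1 and SFTPA2 are nearly identical, so the SFTPA1 value may hold both. Cell cycle genes were lower as a list (median -0.20, 23 of 26 below 0, camera adjusted p = 7.7e-04, adjusted p = 0.394 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone by limma; MKI67 had -0.62, CCNE1 -0.51, MCM5 -0.47 and MCM7 -0.43. Genes induced by ERK signalling were lower (median -0.18, 14 of 17 below 0, camera adjusted p = 0.0267, adjusted p = 0.394 with an estimated correlation), again with 0 called over all genes and 0 adjusted over the list alone, and FOSL1 at -0.62 and EGR1 at -0.55. NF-kB and chemokine genes were lower as well (median -0.34, camera adjusted p = 0.0267, adjusted p = 0.506 with an estimated correlation), with 0 called over all genes and 5 of 13 adjusted over the list alone. CCL2 had -0.82 and CCL20 -0.67, while CXCL1 went the other way at 0.55. The other 20 lists did not pass in HCC4019, with camera adjusted p of 0.0854 (mesenchymal genes) or more. With fry only the alveolar type II list passed in HCC4019 (fry adjusted p = 0.0343). The fry adjusted p was 0.0646 for cell cycle, 0.0646 for ERK output and 0.181 for NF-kB and chemokine genes.

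The HCC4019 count depended on the processing, at 0 with median scaling, without a detection filter, with the replicate number as a block and with the line fitted alone, and at 114 without background correction. The count was also lost with fewer arrays: leaving out any of 7 arrays (HCC4019 knockdown replicate 2, either HCC4019 control, or any H3255 array) gave 0 genes, and leaving out HCC4019 knockdown replicate 1 gave 13, of which 2 were among the 15. The changes themselves moved less, with RARRES1 at 1.58 to 1.75, S100P at 1.37 to 1.52 and SFTPB at -2.01 to -1.47, and the H3255 arrays enter them only through the normalization, the detection filter and the shared spread. Without background correction GSTA2 had 1.02, AXIN2 0.57 (under the bound above), SLX4IP 0.49, CD82 0.72, TLR1 0.57, CEMIP -0.56 and LRRN4 -0.67, and with the mean of its probes ASS1 had 0.89. Among the lists, NF-kB and chemokine genes missed the threshold without HCC4019 knockdown replicate 1 (camera adjusted p = 0.547) or control replicate 1 (0.403), ERK output genes without HCC4019 knockdown replicate 2 (0.107) or control replicate 1 (0.388), and cell cycle genes without HCC4019 control replicate 2 (0.0666).

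The same comparison in H3255 gave larger changes. The epithelial GABA receptor subunit GABRP rose by 3.19 ± 0.294 (9.12-fold, detected on 1 of the 2 control arrays), the TEAD cofactor VGLL1 by 3.10 ± 0.142 (8.55-fold) and KRT4, a keratin of stratified epithelia, by 3.02 ± 0.177 (8.09-fold). The imprinted non-coding RNA H19 rose by 2.56, the complement factor CFB by 2.24, and the cell surface protein PSCA by 2.19. ACSS1, a mitochondrial acetyl-CoA synthetase, rose by 2.16, the uroplakin UPK2 by 2.04, the proton pump subunit ATP6V1B1 by 1.92 and SCARA3 by 1.90. PSCA, ACSS1 and UPK2 were detected on 1 of the 2 control arrays. The largest fall was in KRT16P2 (-2.73 ± 0.124), with the same caution on its probes, then C11orf96 (-2.67), the transcription factor TFAP2D (-2.36) and CEMIP (-2.35 ± 0.130, or 5.09-fold). PLAT, tissue plasminogen activator, had -2.15 and DLC1 -2.13, and both passed the threshold. The mucin-type glycosyltransferases GALNT4 (-2.10) and GALNT6 (-2.01), the thrombin inhibitor SERPIND1 (-2.01) and GOLGA8A (-1.92), whose probe may read close relatives, fell too. DLC1 and SERPIND1 were detected on 1 of the 2 knockdown arrays. In limma, 612 of 11615 genes passed the threshold, 270 higher and 342 lower, with adjusted p down to 1.4e-04. In 52.5% of the genes the knockdown and control arrays did not overlap, against 33.3% by chance.

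**Figure D2:**
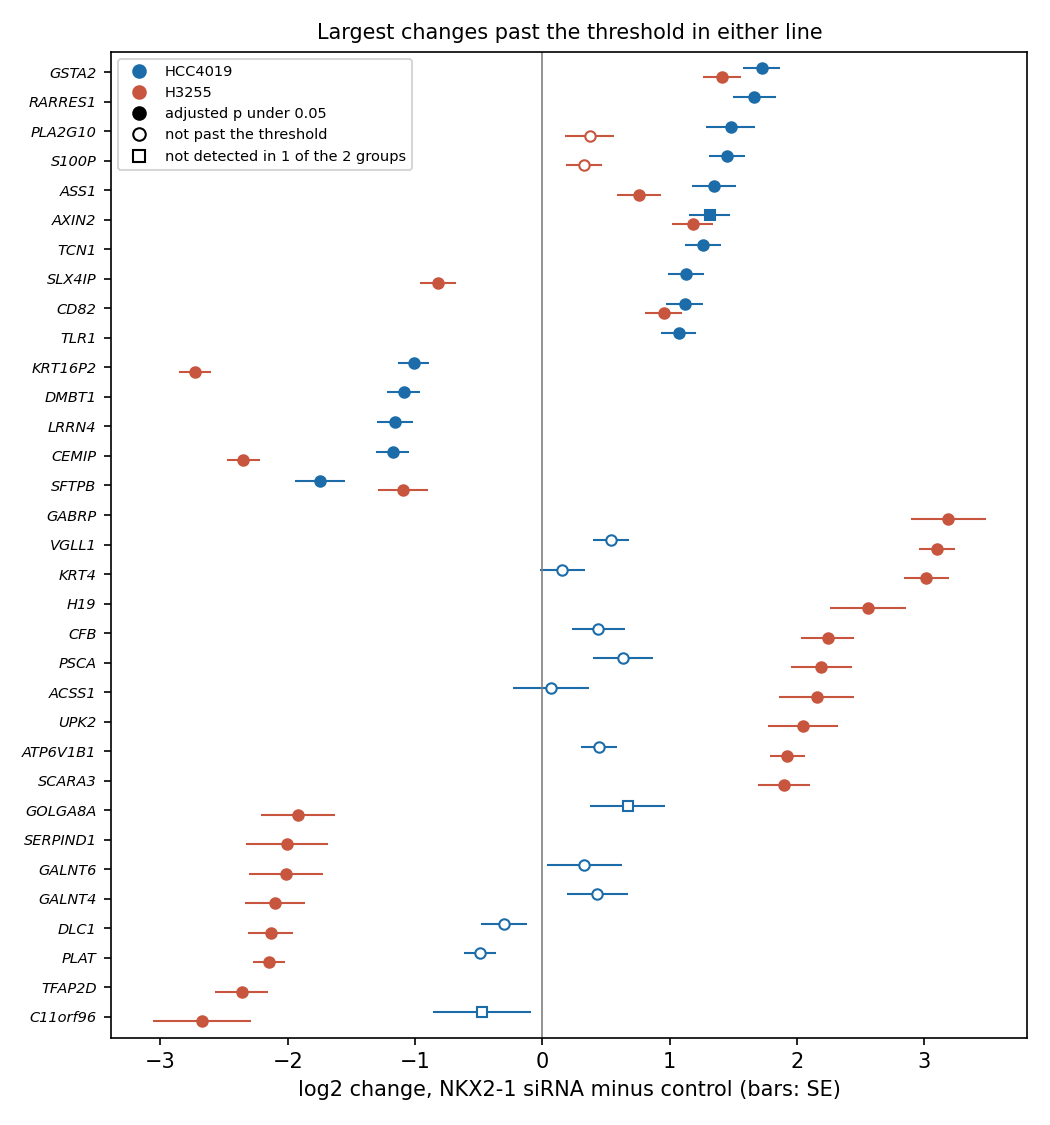
Log2 change with SE (NKX2-1 siRNA minus control, n = 2 arrays per group) of the named genes of either line, in HCC4019 (blue) and H3255 (red). Filled points have a limma adjusted p under 0.05, squares mark genes not detected in 1 of the 2 groups, and a point is left out where neither group detected the gene; GABRP reached 3.19 in H3255 and SFTPB -1.75 in HCC4019.

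Surfactant and other alveolar type II genes fell in H3255 as well. SFTPA1 fell by 1.56 ± 0.188 (limma, adjusted p = 0.0060), the phosphate transporter SLC34A2 by 1.42 ± 0.165 and SFTPB by 1.09 ± 0.197, while SFTPD had -0.98 without passing the threshold (limma, adjusted p = 0.0735). Of 15 members 6 were lower over all genes and 0 higher, and adjusted over the list alone 9 were lower and 1 was higher, or 8 and 1 of the 14 without NKX2-1 (list median -0.59, camera adjusted p = 9.9e-05, adjusted p = 0.192 with an estimated correlation). ERK output genes fell as a list (median -0.30, camera adjusted p = 7.2e-04, adjusted p = 0.192 with an estimated correlation). Of its 17 members 3 fell over all genes and 7 adjusted over the list alone. ETV1, an ETS factor not detected on the knockdown arrays, fell at least 3.47-fold, the feedback inhibitor SPRY4 fell 2.14-fold and the ETS factor ETV5 by 0.98 on the log2 scale. ETV5 is also on the alveolar type II list, so its fall is counted in both lists. Interferon response genes were higher (median 0.20, camera adjusted p = 0.0364, adjusted p = 0.291 with an estimated correlation), with 2 of 20 called over all genes and 2 adjusted over the list alone, IFIT2 at 0.81 and IFI35 at 0.67.

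**Figure D3:**
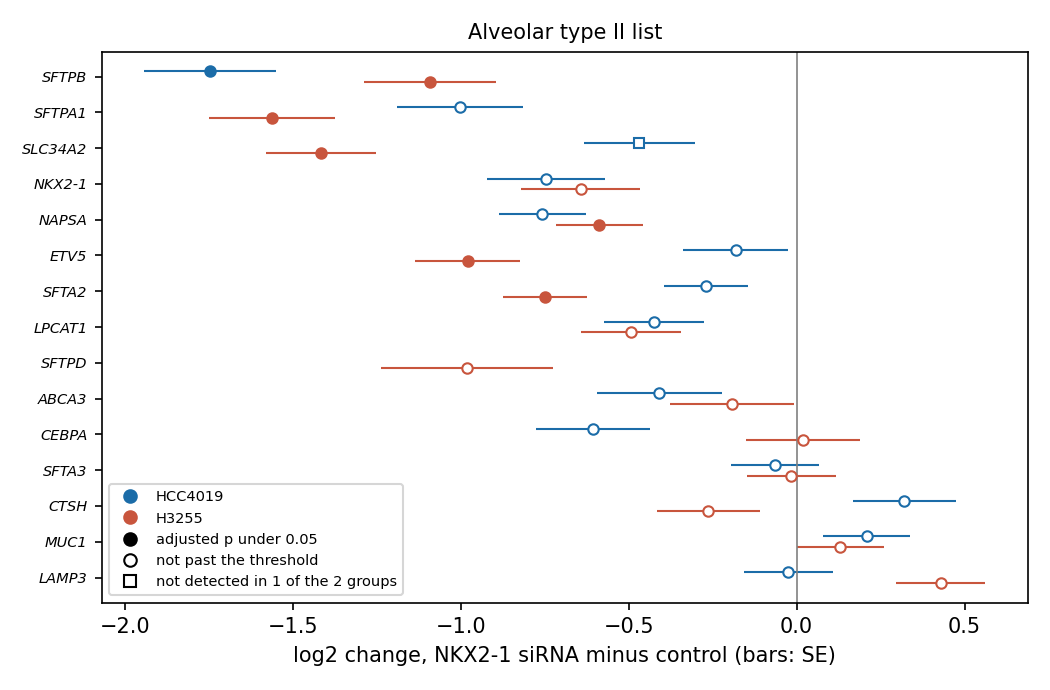
Log2 change with SE (NKX2-1 siRNA minus control, n = 2 arrays per group) of the measured members of the alveolar type II list in HCC4019 (blue) and H3255 (red). Filled points have a limma adjusted p under 0.05, squares mark genes not detected in 1 of the 2 groups, and SFTPD in HCC4019 is left out because neither group detected it; SFTPB was lower in both lines, by 1.75 in HCC4019 and 1.09 in H3255 on the log2 scale.

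In H3255 no other list passed camera. Of 14 secreted lung proteins 4 rose and 5 fell over all genes, and 5 and 6 adjusted over the list alone (camera adjusted p = 0.756). The protease inhibitor SLPI (1.66) and the siderophore-binding LCN2 (1.24) rose, as did C3 and the copper carrier CP, while SFTPA1, SFTPB, NAPSA, SFTA2 and TFPI fell. Airway secretory genes CYP4B1 (1.19), AGR2 (0.87) and SPDEF (0.62) rose, 3 of 9 over all genes and 5 adjusted over the list alone, all higher (camera adjusted p = 0.0595, fry adjusted p = 0.0337). Of 14 lung transcription factors FOXA2 fell by 1.15, and ELF3 (0.78) and SOX2 (0.62) rose, with 4 adjusted over the list alone. EGFR, the receptor kinase, fell by 0.85 (limma, adjusted p = 0.0312), the only one of 14 receptor kinases and ligands called, with 5 adjusted over the list alone. Among epithelial junction genes CLDN1 fell by 0.81 and CGN rose by 0.76, with 2 of 14 also called adjusted over the list alone. CXCL2, a chemokine, fell by 1.35 in the NF-kB list, CCN1 rose by 0.82 among mesenchymal genes, and the glucose transporter SLC2A1 rose by 0.57 in the hypoxia list.

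Markers of other cell types were tested where detected, for 2 of 13 leukocyte, 3 of 12 fibroblast, 4 of 13 squamous, 2 of 11 neuroendocrine and 5 of 10 endothelial genes, and none of these lists passed camera in either line. The endothelial gene VWF was not detected on the H3255 control arrays and rose at least 2.07-fold (limma, adjusted p = 0.0066). In H3255 p53 targets (camera adjusted p = 0.0863), NF-kB and chemokine genes (0.150), mesenchymal genes (0.162) and cell cycle genes (0.172) did not pass either. Genes of the unfolded protein response, sterol and fatty acid synthesis, hypoxia and glycolysis, epithelial junctions, gastrointestinal differentiation, MHC class II and thyroid and brain, and the reference genes, had camera adjusted p of 0.541 or more in H3255 and 0.322 or more in HCC4019.

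The H3255 count was 271 with the line fitted alone, 279 without a detection filter, 299 with the replicate block within lines and 247 when a log2 change of at least 1 was also asked for, against 1180 without background correction, 1177 with the authors' processed values and 1210 with an intensity trend and robust variances; median scaling gave 149 higher and 297 lower genes. Sizes were smaller without background correction, with GABRP at 1.88, VGLL1 at 2.06, KRT4 at 2.17, CFB at 1.27, PSCA at 1.16, ACSS1 at 1.07, UPK2 at 1.01, ATP6V1B1 at 1.24, SCARA3 at 1.17, CYP4B1 at 0.53, GALNT4 at -1.38, SERPIND1 at -1.04, and ETV1 at -0.87 and VWF at 0.57, both under the bounds above; DLC1 and GOLGA8A also moved by over 1.5 times, and with the authors' processed values had -1.02 and -1.01. Without H3255 knockdown replicate 1 or 2 it was 390 or 132, without H3255 control replicate 1 or 2 188 or 112, and without HCC4019 control replicate 1 or 2 359 or 337. Many calls named in H3255 also missed the threshold without some array: ACSS1, UPK2, SFTPA1 and VWF without 1 of the 8, SERPIND1 without 2, C11orf96, GALNT6, AGR2, FOXA2, SPRY4 and ETV5 without 3, GOLGA8A, SFTPB and CCN1 without 4, CYP4B1, ELF3 and IFIT2 without 5, EGFR, CLDN1 and CGN without 6, SOX2 without 7, and IFI35 and SLC2A1 whichever of the 8 was left out (limma, adjusted p up to 0.172), and the interferon list without H3255 knockdown replicate 1 (camera adjusted p = 0.0940) or 2 (0.179).

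The next comparison asked whether the changes were shared by the lines. Of the genes called in both, 4 rose in both (ASS1, AXIN2, CD82 and GSTA2) and 3 fell in both (CEMIP, KRT16P2 and SFTPB). ASS1 stays uncertain, since its 3 probes differ in sign in H3255. Independent lists would share 0.232 and 0.147 genes. Both lines were fitted with 1 spread per gene, so genes with a small spread are called more easily in both, and the excess was not tested against this. SLX4IP was called in opposite directions, 1.13 in HCC4019 and -0.82 in H3255. Across all 11615 genes the changes of the lines correlated weakly (Pearson r = 0.064, covariance 0.00737), where genes are not independent replicates, and the lines share no arrays. The sign was the same for 59.6% of the genes called in H3255 and for 50.7% of all genes. On leaving out HCC4019 knockdown replicate 2 the correlation became -0.000213. Without HCC4019 knockdown replicate 1 the overlap was 4, and on leaving out any of the 7 other arrays it could only be 0, since no HCC4019 gene was then called.

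**Figure D4:**
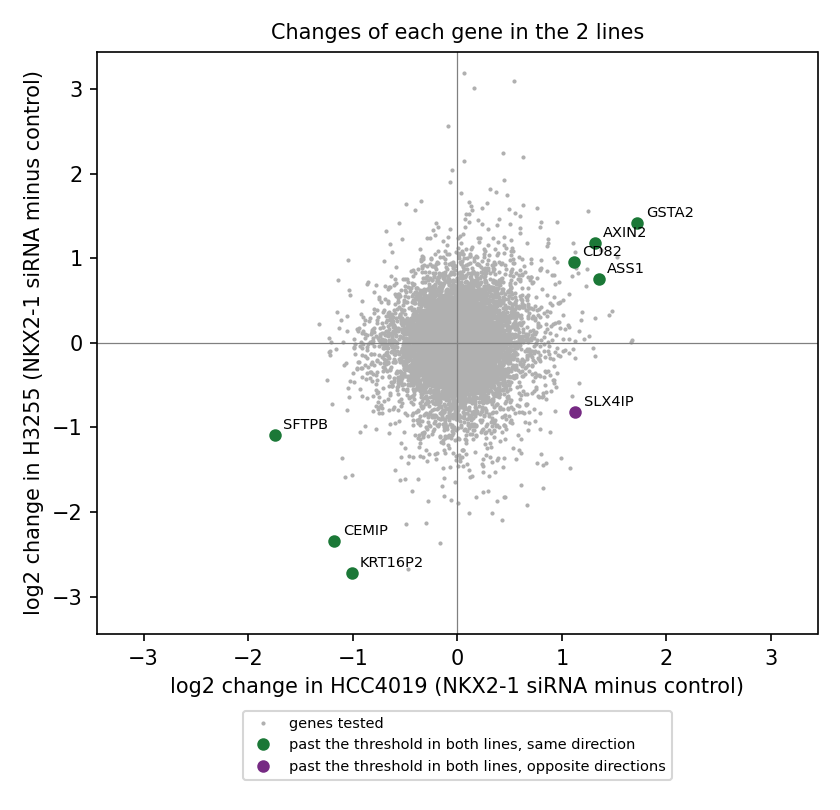
Log2 change in H3255 against that in HCC4019 (NKX2-1 siRNA minus control), with a grey point per gene tested, including genes near background. Green points passed the limma threshold in both lines with the same direction, 4 higher and 3 lower, and SLX4IP (purple) with opposite directions; over all genes r was 0.064.

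Averaged over both lines, the genes that rose, with knockdown apart from control arrays in both lines, were led by VGLL1 (1.82), KRT4 (1.59), GSTA2 (1.57), PSCA (1.41), CFB (1.34), ceruloplasmin CP (1.27), RASSF9 (1.23) and the matrix metalloprotease MMP7 (1.19). Those that fell were led by KRT16P2 (-1.87 ± 0.087), CEMIP (-1.76), SFTPB (-1.42), thrombomodulin THBD (-1.33), PLAT (-1.32), SFTPA1 (-1.28), HIP1 (-1.24) and DLC1 (-1.22, detected on 1 array of each HCC4019 group). The averages of VGLL1, KRT4, KRT16P2, PLAT and DLC1 came mostly from H3255. Their changes also passed the limma threshold for the difference (H3255 minus HCC4019, 2.56, 2.86, -1.72, -1.66 and -1.83). CFB and PSCA also rose more in H3255 than on average, but did not pass for the difference. BCAS1 and AXIN2 (higher) and the lipid transporter MFSD2A and ETV1 (lower) passed on average as well, without a size here: AXIN2 was not detected on the HCC4019 control arrays, BCAS1 not on the H3255 control arrays, and MFSD2A and ETV1 on no HCC4019 array. In limma 322 genes passed the threshold, 172 higher and 150 lower. Alveolar type II genes fell (7 of 15 over all genes, 8 adjusted over the list alone, or 6 and 7 of the 14 without NKX2-1, median -0.46, camera adjusted p = 1.2e-06, adjusted p = 0.108 with an estimated correlation). ERK output genes fell too (3 of 17 over all genes, 6 adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.108 with an estimated correlation). ETV5 is counted in both the alveolar type II and the ERK output list. NF-kB and chemokine genes were lower (camera adjusted p = 0.0168, adjusted p = 0.350 with an estimated correlation), with CXCL2 called over all genes and 4 genes adjusted over the list alone. Interferon response genes were higher (camera adjusted p = 0.0168, adjusted p = 0.249 with an estimated correlation), IFIT2 and IFIT3 being called over all genes and adjusted over the list alone. Mesenchymal genes were also higher (median 0.21, camera adjusted p = 0.0173, adjusted p = 0.350 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone, and THBS1 at 0.72. The other 19 lists did not pass on average, with camera adjusted p of 0.0575 or more.

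The average count was 120 without a detection filter, 74 with the replicate block within lines, 772 without background correction and 46 with a log2 change of at least 1. It was 191 or 80 without H3255 knockdown replicate 1 or 2, 91 or 85 without H3255 control replicate 1 or 2, 105 without HCC4019 knockdown replicate 2, and 54 or 69 without HCC4019 control replicate 1 or 2. On average, GSTA2 missed the threshold without H3255 knockdown replicate 1 or 2, RASSF9 without 2 of the 8 arrays and BCAS1 without 4. IFIT2 and the ERK output genes SPRY4 and ETV5 each missed it without 7, and IFIT3 whichever was left out. The interferon list missed it without 2 arrays, the mesenchymal list without 3 and the NF-kB list without 4, and without background correction GSTA2 had 0.93, PSCA 0.73, CFB 0.83, RASSF9 0.78 and DLC1 -0.60.

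The difference between the lines was then tested directly. The change of KRT4 was 2.86 ± 0.251 higher in H3255, that of VGLL1 2.56 ± 0.200 and that of LRRC26 1.97 ± 0.209, all 3 detected in both lines on every array. GABRP and SCARA3 also passed, but neither was detected in HCC4019, so no size is given. Changes lower in H3255 included GALNT4 (-2.53 ± 0.338) and TENT4B (-2.26). HAND1, ZNF641 and TFAP2D passed too, without a size, since HAND1 and ZNF641 were not detected on the HCC4019 control arrays and TFAP2D on no HCC4019 array. In limma 37 of 11615 genes passed, 12 higher and 25 lower in H3255, with adjusted p down to 0.0175. Among the gene lists, cell cycle genes differed (median 0.29 higher in H3255, camera adjusted p = 0.0031, adjusted p = 0.643 with an estimated correlation), with 0 of 26 called over all genes and 0 adjusted over the list alone, and the other 23 lists had camera adjusted p of 0.297 or more. No list passed fry for the difference. The count of 37 became 531 without background correction, where KRT4 had 2.01, VGLL1 1.62, GALNT4 -1.71 and TENT4B -1.51, and 0 with a replicate block. It was 70 without HCC4019 knockdown replicate 2, 1 without either H3255 control and 0 without any other array, and the cell cycle list missed the threshold without HCC4019 control replicate 2 (camera adjusted p = 0.0518) or H3255 knockdown replicate 1 (0.0595).

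The control arrays of the lines differed in 7113 of 11615 genes, 3569 higher and 3544 lower in H3255 (limma). MGP, matrix Gla protein, was at least 294-fold higher in H3255, SNRPN at least 166-fold, the serine synthesis enzyme PHGDH at least 164-fold and SHISA2 at least 123-fold, none being detected on the HCC4019 control arrays. PPP1R1B was higher by 9.28 ± 0.284, detected on 1 of the 2 HCC4019 control arrays. The antimicrobial peptide DEFB1 was at least 439-fold lower in H3255, the aldehyde dehydrogenase ALDH3A1 at least 266-fold, the MHC class II chaperone CD74 at least 239-fold and TSPAN7 at least 177-fold, none being detected on the H3255 control arrays. CLDN10 was lower by 7.92 ± 0.182, expressed as -7.92 on the log2 scale, and was detected on 1 of the 2 H3255 control arrays. All 10 had an adjusted p of 1.0e-06 or below in limma. SNRPN shares its locus with SNURF, so its probe may read both. NKX2-1 itself was higher in the H3255 controls by 0.66 ± 0.177 (limma, adjusted p = 0.0121). The count moved by over 1.5 times when a log2 difference of at least 1 was asked for, to 3675 or, with the adjusted p as well, 3670. Without background correction the log2 differences were 6.93 for MGP, 6.32 for SNRPN, 6.01 for PHGDH and SHISA2, -7.14 for DEFB1, -6.51 for ALDH3A1, -6.54 for CD74 and -6.09 for TSPAN7, all under the bounds above, and -6.21 for CLDN10, and with the mean of its probes PPP1R1B had 5.22.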

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

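The comparison of the depth of the knockdown between lines and the test of a shared response were chosen only after the results were seen, as was the limit to splits with 2 arrays of each line on each side, and the other tests in this part were written beforehand.

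The changes of 18 named genes differed between the lines in limma (H3255 minus HCC4019, log2). They were lower in H3255 for GALNT4 (-2.53), HAND1 (-2.28), ZNF641 (-2.27), TENT4B (-2.26), TFAP2D (-2.20), SLX4IP (-1.95), DLC1 (-1.83), KRT16P2 (-1.72), PLAT (-1.66), RARRES1 (-1.65) and ETV1 (-1.58). They were higher in H3255 for ATP6V1B1 (1.48), SLPI (1.55), LRRC26 (1.97), SCARA3 (1.97), VGLL1 (2.56), KRT4 (2.86) and GABRP (3.12). RARRES1 was not detected in H3255, TFAP2D, ETV1, SCARA3 and GABRP were not detected in HCC4019, and HAND1 and ZNF641 were not detected on the HCC4019 control arrays, so the values of these 7 set a change against probes near background and are not sizes. Among probes without a single gene symbol, which no comparison used, 114 of 2939 (3.88%) passed the threshold in H3255 in a fit of all kept probes, 42 higher and 72 lower, and 0 passed in HCC4019. These shares were close to those of probes with 1 symbol in the same fit, 626 of 15496 (4.04%) in H3255 and 6 of 15496 in HCC4019.

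More genes were called in H3255 than in HCC4019, 612 against 15. The excess was smaller at an unadjusted p under 0.05 in limma (2500 against 1313) and at a log2 change of at least 1 (308 against 77). A smaller spread between replicates in H3255 could not give more calls here, because both lines were tested with 1 shared spread per gene (median SE 0.166 in both). The median replicate SD was 0.115 (control) and 0.127 (knockdown) in HCC4019, and 0.114 and 0.128 in H3255. The SD of the changes after the replicate noise is removed, which measures their size, was 1.76 to 1.87 times as large in H3255. Dim probes do not account for the excess, with 17.7 times as many genes called in H3255 among genes with a detection p under 0.01 on all 8 arrays. Normalization does not account for it either, with 29.5 times under cyclic loess and 446 genes against 0 under median scaling; the lowest ratio over 4 settings, 10.4, came without background correction, which keeps quantile normalization. A deeper knockdown of NKX2-1 in H3255 was not seen in the RNA, since both probes fell less there than in HCC4019. The dimmer probe had -0.96 against -1.56 and the brighter -0.64 against -0.75. With the mean of the probes the fall was smaller in H3255 by 0.35 ± 0.181 (SE). This is under 2 SE from 0, so the rule set for this comparison could not tell, and the protein was not analysed here. A difference in how the lines depend on NKX2-1 may therefore remain, and it was not tested separately from other differences between the lines.

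The changes of the lines correlated weakly across genes. Measurement noise alone does not account for this, since the correlation after removing the noise of each line was at most 0.129. A response shared in part and smaller in HCC4019 may contribute: genes called higher in H3255 had a median of 0.15 in HCC4019 (camera p = 1.4e-09, and 0.00238 with an estimated correlation), but genes called lower had -0.020 (camera p = 0.199). The difference of the medians was 0.171, so the sharing was seen for genes that rose and could not be told for genes that fell.

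Cell cycle genes were lower in HCC4019 and not in H3255, with a median difference of 0.29 over the list. The normalization does not account for it, as the median was 0.279 with median scaling and 0.310 with cyclic loess, and 0.243 at the lowest with the authors' processed values, which are also quantile-normalized. No single array accounts for the size of the median difference, as it stayed between 0.237 and 0.347 on leaving each out. The list's call did depend on single arrays, as given above. Slower division of HCC4019 cells may be reflected here, as a hypothesis, but cell numbers were not analysed here. The list did not pass for the difference with an estimated correlation (camera adjusted p = 0.643) or with fry. The version with an estimated correlation was stricter also where the estimate was low, so it cannot tell whether correlation between genes made the call.

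The 322 genes changed on average over both lines were set against other splits of the arrays. Of the 18 splits with 2 arrays of each line on each side, 1, the real one, gave as many genes, and the highest of the others gave 37. That split swaps the siRNA groups in 1 line, so it is the difference between the lines and not a random grouping, and the next highest gave 10, but 18 splits are too few for a share under 5%.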

How the results depend on the processing

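Leaving NKX2-1 out of the alveolar type II list was chosen after seeing the data, and all other alternatives were planned. The control arrays kept a count within 1.5 times of 7113 except under thresholds on the size of the difference (3675, and 3670 with the adjusted p). Named genes other than NKX2-1 within a line gave, over all alternatives, 3511 results with the same direction and side of the threshold, 646 that no longer passed, 166 that newly passed and 5 that changed sign. The alveolar type II list passed camera in both lines and on average under every alternative except an estimated correlation, also without NKX2-1, the target of the siRNA (medians -0.34, -0.54 and -0.43). What moves the counts under each alternative was not tested.

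Counts below are in the order HCC4019, H3255, difference between lines, average, and both lines in the same direction, leaving out those within 1.5 times of the main 15, 612, 37, 322 and 7. Where HCC4019 has 0 genes, the count in both lines can only be 0. Without background correction they were 114, 1180, 531, 772 and 36, and with the authors' processed values 113, 1177, 522, 765 and 36. An offset of 50 gave 39 in HCC4019, 254 for the difference, 494 on average and 18 in both, and saddle-point normexp 42, 251, 493 and 20. Median scaling gave 0 in HCC4019 (1071 at an unadjusted p under 0.05 in limma), 18 for the difference and 0 in both, and moved the split in H3255 to 149 higher and 297 lower. Without a detection filter they were 0 (1545 unadjusted), 279, 3, 120 and 0. A detection p under 0.01 on all 8 arrays, stricter in both respects than the main filter, gave 46 in HCC4019, 270 for the difference and 19 in both. The difference gave 14 with all probes and 75 with the mean of probes. An intensity trend with robust variances gave 97, 1210, 494, 750 and 38. Each line fitted alone gave 0 (1280 unadjusted), 271 and 0 in both, and can give no difference, average or control comparison. A log2 change of at least 1 in place of the test gave 77, 308, 535, 48 and 13, and with the test 247 in H3255 and 46 on average.

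With a replicate block within each line the counts were 0 (1280 unadjusted), 299, 0 (1881 unadjusted), 74 and 0. With a replicate block across both lines HCC4019 gave 0 (1326 unadjusted), the difference 0 (1937 unadjusted) and both lines 0. After normalization, deviations of arrays with the same number correlated at -0.027 to 0.050, so no pairing by number was seen there. Before normalization, the median signal was higher in replicate 1 than in replicate 2 of every group. In HCC4019 it was 168.3 against 134.7 (knockdown) and 175.0 against 155.8 (control). In H3255 it was 149.0 against 126.6 and 166.1 against 151.4. At each replicate number the median was also lower on the knockdown array than on the control array of that line. Quantile normalization removes such shifts, so the normalized deviations cannot exclude a batch that follows the replicate number. Whether the shift between knockdown and control arrays came from a batch or from the siRNA was not tested. NKX2-1 passed in both lines without background correction (-0.68 and -0.61), with the processed values (-0.68 and -0.61), on the best of all probes (-1.56 and -0.96), as the mean of probes (-1.15 and -0.80) and with trend and robust variances (-0.75 and -0.64). In H3255 it also passed with an offset of 50 (-0.63), saddle-point normexp (-0.62) and the strict filter (-0.64).

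Leaving out each array in turn gave 0 to 13 genes in HCC4019, 112 to 554 in H3255, 0 to 70 for the difference, 54 to 227 on average and 0 to 4 in both; a lone array is then assumed to vary like the other groups. The correlation across genes ran from -0.000213 to 0.096. Lists past the threshold ran from 2 to 5 in HCC4019, 2 to 4 in H3255, 0 to 1 for the difference and 2 to 6 on average. NKX2-1 in the difference ran from -0.077 to 0.28, and TIE1 on average from -0.41 to 0.017. MARVELD2 in H3255 turned to -0.0094 with the mean of its probes, which point in opposite directions. Of the lists, 0 passed in any contrast with an estimated correlation, fry passed 1 in HCC4019, 0 for the difference and 3 on average, the strict filter 2 in HCC4019 and 5 in H3255, and all probes 2 for the difference. Chip or scan as a block was not run, since the files name neither.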

Other observations

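The test of genes called in H3255 was chosen only after the results were seen.

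Genes called higher in H3255 had the same sign in HCC4019 for 186 of 270, or 68.9%, and genes called lower for 179 of 342, or 52.3%. The lines share no arrays, so the first share does not come from control arrays used for both lines. Both lines received a knockdown pool and a non-targeting pool under the same labels. Whether an effect of the non-targeting pool, or an off-target effect of the knockdown pool, was shared by the lines was not tested.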
